A study of Homo sapiens with 12 samples.

How the data were processed

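RNA was sequenced from 2 human lines, IOSE, labelled as ovarian epithelial cells, and Nthy, labelled as normal thyroid cells. Each line was given PM2.5, airborne particles small enough to reach the deep lung, or served as control, with 3 libraries in each of the 4 groups and 12 libraries in all. The dose, the exposure time, the source of the particles and the treatment of the controls are not given in the sources used here. Libraries were made from total RNA and read as 150 bp pairs on an Illumina NovaSeq, per the labels' protocols. The labels do not say that libraries of a group came from separate cultures, so every p-value measures only the spread between these libraries, which may be technical.

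The authors deposited 1 table of FPKM, fragment counts scaled to the length of the gene and the total of the library, for 58735 genes in the 12 libraries. Per the submitters' processing notes the tools were fastp, HISAT2 2.0.5, StringTie 1.3.3b, featureCounts 1.5.0-p3, DESeq2 1.20.0, edgeR 3.22.5 and GATK 4.1.1.0, with no role or order stated, and the build was hg19. The gene positions in the deposited table match GRCh38 instead: 58690 of the 58735 genes had the same position and strand as in GENCODE release 29. Coordinates below are therefore those of the deposited table, on GRCh38. Whether reads were counted by strand is not given in the sources used here.

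Each FPKM value in the deposited table was a whole multiple of the value of 1 read for that gene and library, within 0.01 read for 100% of values. This gave 15218294 to 19681030 recovered reads per library. The total implied by the authors' FPKM scale was 0.954 to 1.14 times the recovered total, so the deposited values already carried a scaling between libraries. At these depths 1 read on a gene of 1 kilobase was worth 0.0447 to 0.0632 FPKM. Between 19818 and 22720 genes lay above 0 in a library, 2.82% to 4.23% of reads fell on mitochondrially encoded genes, and the 50 most abundant genes took 11.1% to 16.8%. Genes above 0 numbered 19818 to 20222 with PM2.5 and 20648 to 21063 in controls of IOSE, and 22247 to 22720 and 21042 to 21218 in Nthy. The mitochondrial share was 3.70% to 4.03% with PM2.5 and 2.82% to 3.60% in controls of IOSE, and 3.16% to 4.23% and 3.13% to 3.16% in Nthy. The top 50 genes took 16.4% to 16.8% with PM2.5 and 14.6% to 14.8% in controls of IOSE, and 11.1% to 14.1% and 12.5% to 12.7% in Nthy. No pair of replicates agreed within sampling noise, with chi-square per degree of freedom from 4.91 to 119, and every library was counted once.

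The design fixed before the data were examined named a count test as the main test and limma on log2(value + 1) if no counts were present. The table held FPKM and not counts, so the second was used. Values were taken as log2(FPKM + 1), and genes with at least 0.5 FPKM in at least 3 libraries were kept, which left 15706 genes, 12370 of them protein coding. limma 3.58.1 in R 4.3.3 was fitted to all 12 libraries with 1 coefficient per group and a trend of the variance with level, with 8 residual degrees of freedom before moderation. All adjusted p-values for genes are from limma with Benjamini-Hochberg adjustment, and a gene was called past a false discovery rate of 0.05. Fold changes are PM2.5 minus control on the log2(FPKM + 1) scale, which understates the change of genes of low level. The contrasts were PM2.5 against control in IOSE, the same in Nthy, and the Nthy effect minus the IOSE effect. Values for a group are means ± SD of FPKM over 3 libraries unless stated otherwise.

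The 31 gene lists were fixed from textbook knowledge before the data were examined, and 796 of their 796 symbols were in the table. The 29 lists with at least 5 tested members were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were run beside it. Counts of list members are given over all genes tested and adjusted over the list alone. For the lists not past the threshold of the difference between lines only the median and the test are given. List tests of the difference between lines were added after the data were seen.

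Named genes followed a rule fixed in advance. In each line it took the 8 largest rises and 8 largest falls among called genes with a symbol, a mean of at least 2 CPM, and all PM2.5 libraries on one side of all controls. To these it added up to 3 members with the smallest p from each list with a called member or a list past its test. CYP1A1, CYP1B1, HMOX1 and NQO1 were named whatever their result. For the difference between lines it took the 5 largest in each direction past the threshold with a mean of at least 2 CPM. For the lines themselves it took the most abundant members of the thyroid and ovarian lists. Any other gene named below was chosen after its values were seen. Results of some genes that the rule took are not reported here.

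The fit was tested on simulated data for the 15706 genes, with 200 genes changed in each line. With the spread of IOSE it recovered 24% of 1.5-fold and 77% of 3-fold changes, with 7 false among 115 calls (6.09%). With the spread of Nthy it recovered 32% and 86%, with 112 false among 240 calls (46.7%). In each simulation all libraries of a line had the mean dispersion of its control and PM2.5 groups. The unequal spread of the 2 Nthy groups was therefore not simulated. With 1 weight per group the Nthy simulation recovered 15% and 69%, with 27 false among 114 calls, and the IOSE simulation 58% and 91%, with 46 false among 213 calls.

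Other settings chosen in advance were upper quartile scaling, size factor scaling, other filters, a pseudocount of 0.1, each line fitted alone, the replicate number as a block, each library left out in turn, a minimum fold, and other list tests. Added after the data were seen were limma-voom on the recovered reads, a correction for GC content (a spline with 4 degrees of freedom per library, for the 99.9% of tested genes with a value), protein-coding genes only, 1 weight per group, and a filter of at least 0.5 FPKM in at least 3 libraries of each line, which left 11892 genes. Planned runs of DESeq2 and edgeR were meant for deposited counts and were not made on the recovered reads, where limma-voom was run instead. GC content was taken from GENCODE release 29. Gene lengths and positions were those of the deposited table, and overlaps were sought among the tested genes. A gene was treated as uncertain if named pseudogene copies or an overlapping gene could share its reads. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.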

Results

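The transcriptomes of 2 human lines, IOSE and Nthy, were measured with and without PM2.5 in order to look for the molecular basis of urogenital and endocrine disease in women attributed to these particles. IOSE was described as ovarian epithelial cells and Nthy as normal thyroid cells. Each line had 3 libraries with PM2.5 and 3 control libraries, at 15218294 to 19681030 recovered reads each. Libraries with PM2.5 had fewer genes above 0 than controls in IOSE (19818 to 20222 against 20648 to 21063) and more in Nthy (22247 to 22720 against 21042 to 21218). All values below are FPKM, as mean ± SD of 3 libraries, and fold changes are on the log2(FPKM + 1) scale.

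In the control libraries the lines differed in several genes that mark thyroid or epithelial cells. PAX8, a thyroid and kidney transcription factor, stood at 29.6 ± 1.63 in Nthy and 0.0352 ± 0.0117 in IOSE, and FOXE1, another thyroid transcription factor, at 25.2 ± 3.65 and 1.59 ± 0.189. NKX2-1, the third factor of that set, went the other way, with 10.4 ± 0.099 in IOSE controls and a listed value of 0 in all Nthy controls. Thyroglobulin (TG) was at 0.0367 ± 0.00751 in Nthy controls. The keratins of simple epithelia were abundant in Nthy, with KRT7 at 276 ± 23.6, KRT18 at 398 ± 40.1 and KRT8 at 402 ± 37.4. In IOSE controls KRT7 was listed at 0, KRT18 was at 45.4 ± 0.393 and KRT8 at 4.52 ± 0.0749. Other genes of the epithelial junction list did not follow the keratins. JUP was at 64.5 ± 2.71 in IOSE and 27.2 ± 2.17 in Nthy controls, and DSP at 6.45 ± 0.501 and 1.19 ± 0.0871. CLDN1 was higher in Nthy (30.2 ± 2.19 against 3.28 ± 0.132). CDH1 (0.0151 in IOSE and 0.0966 in Nthy) and EPCAM (0.287 and 0.315) were low in both lines. Of the ovarian and mesothelial genes, LHX2 (11.8 ± 0.558) and HOXC9 (18.0 ± 0.125) were the most abundant transcription factors of the ovarian list in IOSE, where WT1 was at 0.0314 ± 0.0204, while mesothelin (MSLN) was at 11.6 ± 1.43 in Nthy. Of the markers of other cell types, 3 of 17 immune and 2 of 12 endothelial genes lay above the filter, so these lists were not tested, while 8 of 13 fibroblast and pericyte and 6 of 10 granulosa markers did. The highest group mean was 3.77 for the immune gene CD14 and 44.7 for EGFL7, an endothelial gene.

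In IOSE the ferritin genes, the transferrin receptor and genes of the ATF4 stress response rose with PM2.5, the last as a list at adjusted p = 0.318 with an estimated correlation. Ferritin heavy chain FTH1, the iron-storing subunit, rose from 432 ± 10.8 to 1655 ± 107 FPKM (log2 fold change 1.93, SE 0.15, adjusted p = 0.000223), and the light chain FTL rose from 4956 ± 125 to 13914 ± 957 (1.49, SE 0.15, adjusted p = 0.000923). Both ferritin genes have near-identical copies, 25 named for FTH1 and 16 for FTL, so part of their reads may be split among loci. TFRC, the transferrin receptor that brings iron into the cell, rose from 5.21 ± 0.605 to 18.7 ± 2.02 (1.66, SE 0.22, adjusted p = 0.00291). The stress cytokine GDF15 rose from 28.8 ± 1.06 to 92.6 ± 11.1 (1.64, SE 0.17, adjusted p = 0.000923) and the endoplasmic reticulum chaperone HSPA5 (BiP) from 850 ± 86.1 to 2239 ± 142 (1.40, SE 0.19, adjusted p = 0.00291). The nuclear receptor NR4A2, an immediate early gene, rose from 4.30 ± 0.314 to 20.1 ± 0.518 (1.99, SE 0.22, adjusted p = 0.00136). On GRCh38, FTH1 lies on chromosome 11 at 61959718 to 61967660, TFRC on chromosome 3 at 196027183 to 196082189 and GDF15 on chromosome 19 at 18374731 to 18389176. Haem oxygenase HMOX1 (chromosome 22, 35380361 to 35394214), which degrades haem, had the largest rise of the named genes, from 94.8 ± 2.12 to 539 ± 61.0 (2.49, SE 0.63, adjusted p = 0.0297). Its call was lost without any 1 of the 6 IOSE libraries, with adjusted p from 0.0718 to 0.0977 and a fold change of 2.43 to 2.58, and with no filter (0.0752). The SE rests on a spread shared with the Nthy libraries, and the call was kept with IOSE fitted alone.

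Grouped by list, the ATF4 and integrated stress response genes rose in IOSE, with 16 of 30 members higher, 0 lower and 14 not past the threshold, 18 higher and 1 lower adjusted over the list alone, and a median of 0.53 (camera adjusted p = 2.48e-10; adjusted p = 0.318 with an estimated correlation). Examples were DDIT3 (CHOP), a transcription factor of stress-induced death, at 1.77 (SE 0.27), GDF15, and CEBPB, a partner of ATF4, at 0.69 (SE 0.10). DDIT3 overlaps MARS, MBD6 and MIR616, so its reads are uncertain. NRF2 targets, the antioxidant genes, rose with 8 of 25 higher and 0 lower, 11 and 2 adjusted over the list alone, and a median of 0.42 (camera adjusted p = 7.38e-06; adjusted p = 0.370 with an estimated correlation). They included FTH1, FTL, thioredoxin reductase TXNRD1 (1.08, SE 0.21) and the quinone reductase NQO1, which went from 322 ± 22.1 to 454 ± 14.8 (0.50, SE 0.11, adjusted p = 0.0180). TXNRD1 was not past the threshold without IOSE control 1 (adjusted p = 0.0503). The same held for NQO1 without PM2.5 replicate 1 or 3 or control 1 or 2 (adjusted p from 0.0688 to 0.0747). Immediate early genes rose with 7 of 31 higher and 0 lower, the same 7 and 0 adjusted over the list alone, and a median of 0.21 (camera adjusted p = 0.000499; adjusted p = 0.478 with an estimated correlation), among them NR4A3 at 1.02 (SE 0.16) and KLF4 at 0.65 (SE 0.10).

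Replication-dependent histone genes, whose transcripts normally lack a poly(A) tail, rose in IOSE with 5 of 11 higher and 0 lower, 6 and 0 adjusted over the list alone, and a median of 0.46 (camera adjusted p = 0.00125; adjusted p = 0.318 with an estimated correlation). HIST1H1C went from 55.8 ± 8.68 to 98.4 ± 6.68 and HIST1H2AC from 3.83 ± 0.771 to 7.42 ± 0.755. HIST1H1C lost its call without PM2.5 replicate 1 or 3 or control 1 or 2 (adjusted p from 0.0677 to 0.0768), and HIST1H2AC without control 1 or 3 (0.0587 to 0.0616). Lysosome and autophagy genes rose as a list, with 2 of 34 higher and 0 lower, 1 and 0 adjusted over the list alone, and a median of 0.15 (camera adjusted p = 0.00365; adjusted p = 0.560 with an estimated correlation). The 2 were NPC2, a lysosomal cholesterol carrier, at 0.51 (SE 0.10) and GLA, a lysosomal galactosidase, at 0.66 (SE 0.19). Leaving out a library ended the call of NPC2 for PM2.5 replicate 3 and controls 1 and 3 (adjusted p from 0.0506 to 0.0625), and of GLA for each IOSE library and each Nthy control (0.0604 to 0.133).

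DNA replication genes and fibroblast and pericyte markers fell in IOSE, each at adjusted p = 0.370 with an estimated correlation. DNA replication and G1/S genes had 0 of 32 higher and 10 lower, 1 and 13 adjusted over the list alone, with a median of -0.34 (camera adjusted p = 0.00321; adjusted p = 0.370 with an estimated correlation). The replicative helicase subunit MCM7 went from 60.3 ± 2.78 to 33.3 ± 1.86 (-0.84, SE 0.12), MCM2 from 22.7 ± 1.37 to 11.9 ± 1.45 (-0.88, SE 0.14), and thymidine kinase TK1 from 94.8 ± 3.88 to 46.4 ± 2.81 (-1.02, SE 0.16). MCM7 overlaps AP4M1, MIR25 and MIR93, and MCM2 overlaps TPRA1. Fibroblast and pericyte markers had 0 of 8 higher and 5 lower, also 0 and 5 adjusted over the list alone, with a median of -0.43 (camera adjusted p = 0.00337; adjusted p = 0.370 with an estimated correlation). Collagen III, COL3A1 (chromosome 2, 188974320 to 189012746), fell from 33.6 ± 1.3 to 13.5 ± 0.212 (-1.25, SE 0.08, adjusted p = 9.66e-05). Smooth muscle actin ACTA2, which overlaps FAS and STAMBPL1, fell from 60.8 ± 3.28 to 20.5 ± 2.83 (-1.53, SE 0.12, adjusted p = 0.000223). The largest fall was that of MT-ATP8, a short subunit gene of the mitochondrial ATP synthase that overlaps MT-ATP6, from 54.8 ± 11 to 9.10 ± 1.46 (-2.46, SE 0.47, adjusted p = 0.00968). The potassium channel gene KCNH3 (-1.45, SE 0.13), the adaptor gene KANK2 (-1.32, SE 0.21) and CNIH2, an auxiliary subunit of glutamate receptors (-1.29, SE 0.19), also fell. BAIAP2-DT, a noncoding transcript, at -1.28 (SE 0.24), and C19orf71, at -1.25 (SE 0.34), completed the 8 largest falls. C19orf71 was at -0.81 without IOSE PM2.5 replicate 3, and its call was lost with IOSE fitted alone (adjusted p = 0.0739). BAIAP2-DT was not past the threshold without control 3 (adjusted p = 0.0502), nor C19orf71 without PM2.5 replicate 1 or 3, any IOSE control, Nthy PM2.5 replicate 1 or any Nthy control (0.0523 to 0.137). Reads of KCNH3 (with MCRS1), CNIH2 (YIF1A), C19orf71 (MFSD12), TXNRD1 (EID3), CEBPB (CEBPB-AS1) and NPC2 (ISCA2) could be shared with the overlapping genes in brackets.

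The other lists were not past the threshold in IOSE, though single members were. The extracellular matrix and mesenchymal list had 10 of 38 lower and 0 higher, the same adjusted over the list alone, with a median of -0.04 (camera adjusted p = 0.0899). COL6A1, a collagen VI chain, went from 10.4 ± 0.803 to 5.92 ± 0.407 (-0.72, SE 0.11). Hypoxia and glycolysis genes had 1 of 31 higher and 8 lower, 2 and 13 adjusted over the list alone, and a median of -0.20 (adjusted p = 0.114). Lactate dehydrogenase LDHA fell from 189 ± 4.23 to 120 ± 0.215 (-0.65, SE 0.07) and phosphofructokinase PFKL by 0.75 on the log2 scale, while the glucose transporter SLC2A3 rose from 51.9 ± 1.86 to 146 ± 9.63 (1.47, SE 0.15). Metallothioneins, the metal-binding proteins, had 2 of 10 higher and 0 lower, with a median of 0.04 (adjusted p = 0.0856). MT1X went from 3.62 ± 0.798 to 16.9 ± 3 (1.95, SE 0.42, adjusted p = 0.0164), a call lost without PM2.5 replicate 1 or 3 or any control (0.0503 to 0.0669). Targets of AHR, the receptor of aromatic hydrocarbons, had 2 of 11 higher and 0 lower, a median of 0.00 and a mean of 0.25 (adjusted p = 0.0887). Fry pointed up at adjusted p = 0.0112, and camera with an estimated correlation gave 0.318. Over the 9 members above the filter in each line the IOSE median was 0.50. The AHR-induced cytochrome gene CYP1A1 was at 1.74 ± 0.385 in controls and 1.43 ± 0.124 with PM2.5 (-0.17, SE 0.18, adjusted p = 0.597). CYP1B1 was at 0.614 ± 0.0376 and 1.38 ± 0.310 (0.55, SE 0.24, adjusted p = 0.158). The ER chaperone list had 3 of 23 higher and 3 lower with a median of 0.08 (adjusted p = 0.249), and cholesterol synthesis 0 of 29 higher and 6 lower with -0.05 (adjusted p = 0.568). In the latter the sterol cyclase LSS fell from 18.8 ± 1.63 to 9.37 ± 1.07 and fatty acid synthase FASN from 120 ± 2.58 to 71.6 ± 11.7.

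The remaining IOSE lists are given by median, with the camera adjusted p. Epithelial junction genes had 1 of 13 higher and 2 lower (-0.17, 0.313), the 2 being plakoglobin JUP (-0.97, SE 0.12) and the tight junction gene TJP3 (-0.90, SE 0.13). TGF-beta and YAP early targets had 2 of 20 higher and 2 lower (0.02, 0.646), with the repressor BHLHE40 at 0.94 (SE 0.15). Thyroid genes had 0 of 9 higher and 2 lower (-0.17, 0.249). Values were 0.14 and 0.0916 for steroidogenesis (1 of 12 higher, 0 lower), 0.07 and 0.114 for p53 targets (2 of 24 higher, 0 lower), -0.01 and 0.467 for ovarian surface genes (0 of 14 higher, 1 lower), and -0.18 and 0.628 for cytosolic heat shock (0 of 18 higher, 1 lower). Interferon-stimulated genes had 2 of 28 higher and 2 lower (-0.16, 0.646), NF-kB genes 1 of 24 higher and 1 lower (0.00, 0.659), mitochondrially encoded genes 0 of 13 higher and 1 lower (-0.12, 0.659), and granulosa markers 0 of 6 in either direction (0.01, 0.771). The share of reads on mitochondrially encoded genes was 3.70% to 4.03% with PM2.5 and 2.82% to 3.60% in controls. With group weights more members were called, 8 higher and 9 lower among apoptosis regulators, 4 and 12 among interferon-stimulated genes, 6 and 16 in hypoxia and glycolysis and 3 and 9 in the respiratory chain, in a fit that had 46 false among 213 simulated calls. In 5 lists the median, mean and test differed in sign. MYC and ribosome biogenesis genes had 1 of 29 higher and 1 lower, a median of -0.03 and a mean of 0.04 (adjusted p = 0.467). Ribosomal proteins had 0 of 55 higher and 1 lower, a median of -0.01, a mean of -0.04 and a test pointing up (0.618). Respiratory chain genes had 1 of 44 higher and 0 lower, a median of -0.02 and a test pointing up (0.805). Mitosis genes had 0 of 32 higher and 4 lower, a median of 0.03 and a mean of -0.04 (0.869), and apoptosis regulators 0 of 27 higher and 1 lower, a median of -0.02 and a test pointing up (0.920). Adjusted over the list alone, the IOSE counts of higher and lower members were 3 and 1 for AHR targets, 4 and 4 for ER chaperones, 1 and 3 for epithelial junctions, 2 and 3 for TGF-beta and YAP targets, 0 and 4 for thyroid genes, 2 and 1 for p53 targets, 0 and 3 for ovarian surface genes, and 0 and 0 for heat shock and for ribosomal proteins. For the other lists not past the threshold they equalled those over all genes, unless given above.

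In all, limma called 1706 of 15706 genes in IOSE, 430 higher and 1276 lower, and 110 of them changed at least 2-fold on this scale (42 higher, 68 lower). The split of calls was nearer even in other fits, at 2599 higher and 3534 lower with IOSE fitted alone, 2864 and 4014 with group weights, and 1620 and 2489 without Nthy PM2.5 replicate 3. In 1705 of the 1706, every PM2.5 library lay on the same side of every control. Over all genes tested this held for 52.0%, where chance gives 10%. On the first principal component (56.8% of the variance) PM2.5 libraries lay at 21.6 to 23.8 and controls at -25.4 to -19.0. The count was 620, 840 and 598 without PM2.5 replicates 1, 2 and 3, and 476, 793 and 541 without controls 1, 2 and 3. It rose to 3984 without Nthy PM2.5 replicate 2 and 4109 without replicate 3, because the spread is shared between lines, and was 6133 with IOSE fitted alone.

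**Figure D1:**
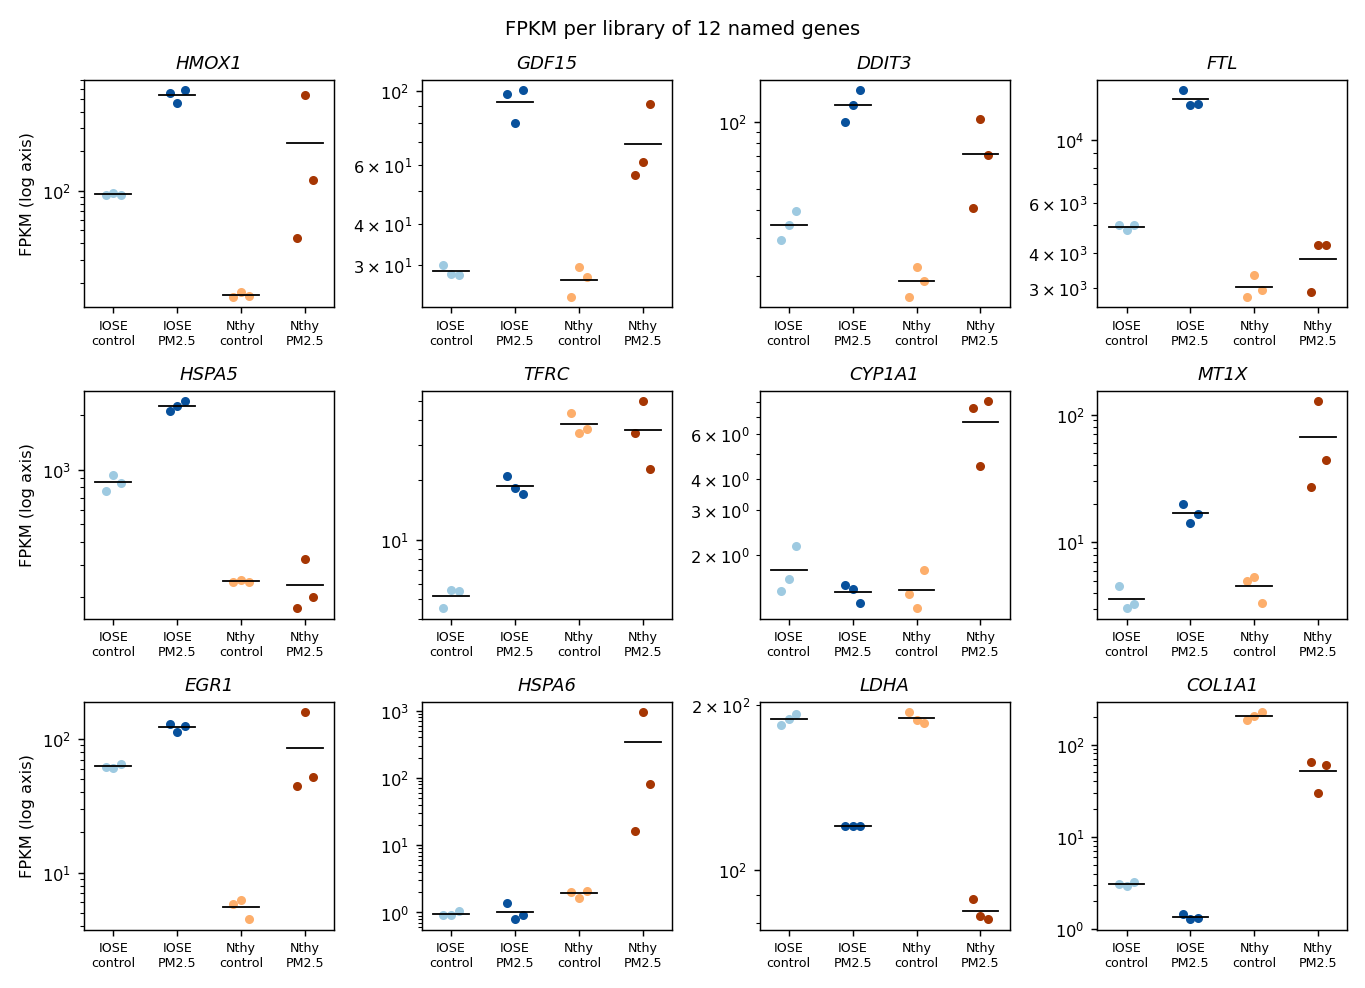
FPKM per library on a logarithmic axis for 12 named genes, in control and PM2.5 libraries of IOSE and Nthy, where each point is 1 library and each black line the mean of 3. FTH1's partner FTL moved from 4956 to 13914 in IOSE, while the Nthy PM2.5 libraries spread widely for HMOX1 (mean 233, SD 264) and HSPA6 (mean 347, SD 518).

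In Nthy, AHR targets and metallothioneins rose with PM2.5 (adjusted p = 0.00302 and 0.0938 with an estimated correlation), and the 3 PM2.5 libraries differed from each other more than those of IOSE. MT1M went from 0.740 ± 0.612 to 42.0 ± 29.6 (4.40, SE 0.45, adjusted p = 0.000405) and MT1X from 4.58 ± 1.09 to 66.2 ± 53.6 (3.31, SE 0.42, adjusted p = 0.00117). SLC30A2, a zinc exporter gene on chromosome 1 at 26037252 to 26046133, rose from 0.350 ± 0.111 to 11.5 ± 5.40 (3.10, SE 0.27, adjusted p = 0.00016). CYP1A1 (chromosome 15, 74719542 to 74725610) rose from 1.46 ± 0.261 to 6.71 ± 1.96 (1.62, SE 0.18, adjusted p = 0.000652) and CYP1B1 from 2.38 ± 0.330 to 11.5 ± 4.66 (1.82, SE 0.24, adjusted p = 0.00137). The cell cycle inhibitor CDKN1A (chromosome 6, 36676460 to 36687339) rose from 52.9 ± 4.28 to 204 ± 50.9 (1.90, SE 0.15, adjusted p = 9.23e-05). HMOX1 went from 16.1 ± 0.757 to 233 ± 264 (3.07, SE 0.63, adjusted p = 0.0101), with 43.7, 534 and 121 in PM2.5 replicates 1, 2 and 3. The heat shock gene HSPA6 went from 1.92 ± 0.219 to 347 ± 518 (5.24, SE 1.01, adjusted p = 0.00754), with 16.2, 944 and 81.6 in PM2.5 replicates 1, 2 and 3. The immediate early gene EGR1 rose from 5.5 ± 0.909 to 85.0 ± 63.5 (3.50, SE 0.36, adjusted p = 0.000389), and GADD45G, a growth arrest gene, went from 0.763 ± 0.297 to 32.6 ± 43.7 (adjusted p = 0.0201). GADD45G was not past the threshold without any 1 Nthy control (0.0586 to 0.0616) or with limma-voom on the recovered reads (0.0796). Metallothionein genes are close in sequence, so their reads could be split between members. Each of these calls was lost when Nthy was fitted alone, as described with the counts. In the fit of all libraries the SE rests on a spread shared by the 4 groups. Nthy PM2.5 libraries varied more (0.403 on the log2 scale, against 0.188 to 0.199 in the other groups). The SE and adjusted p given for Nthy genes therefore tend to be too small. With Nthy fitted alone the SE was 1.39 for HSPA6 (limma adjusted p = 0.154) and 0.862 for HMOX1 (0.166).

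Among the genes that fell in Nthy were a hair keratin, a collagen chain and a glycolytic enzyme. The hair keratin KRT81 (chromosome 12, 52285913 to 52291534), which overlaps KRT86, fell from 212 ± 19.9 to 46.7 ± 7.90 (-2.17, SE 0.13, adjusted p = 3.19e-05). The epithelial sodium channel subunit SCNN1A fell from 15.2 ± 1.28 to 2.70 ± 0.912 (-2.16, SE 0.16, adjusted p = 6.25e-05), and collagen I, COL1A1, from 205 ± 18.4 to 51.7 ± 18.8 (-2.04, SE 0.22, adjusted p = 0.000571). LDHA (chromosome 11, 18394388 to 18408425) fell from 189 ± 4.5 to 84.1 ± 3.90 (-1.16, SE 0.07, adjusted p = 3.19e-05). The differentiation inhibitor ID1 fell by 1.96 (SE 0.41) on the log2 scale (by 1.3 without PM2.5 replicate 2), the MYC antagonist MXD3 by 1.69 (SE 0.27), the plasminogen activator PLAT by 1.65 (SE 0.28), and KRT19, which has 5 named copies, by 1.64 (SE 0.28). PCLAF, a clamp-binding factor of DNA replication, was at -1.64 (SE 0.38, adjusted p = 0.0177), a call lost without control 1 or 2 (0.0523 to 0.0652), and at -1.04 without PM2.5 replicate 3. Reads of SCNN1A (with LTBR), MXD3 (PRELID1 and RAB24), KRT7 (KRT86), AHRR (PDCD6), LIF (LIF-AS1), SQSTM1 (MGAT4B), COL5A1 (COL5A1-AS1), IFIT1 (LIPA) and ATP5F1A (HAUS1) could be shared with the overlapping genes in brackets, and LDHA has 6 named copies.

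By list, 9 rose in Nthy. Metallothioneins had 7 of 10 higher and 0 lower, 8 and 0 adjusted over the list alone, with a median of 2.41 (camera adjusted p = 3.86e-07; adjusted p = 0.0938 with an estimated correlation), MT1F among them at 2.77 (SE 0.33). AHR targets had 9 of 11 higher and 0 lower, the same adjusted over the list alone, with a median of 1.36 (camera adjusted p = 2.21e-10; adjusted p = 0.00302 with an estimated correlation). Their members with the smallest p were SERPINB2, an inhibitor of plasminogen activators (8.02 ± 0.787 to 47.9 ± 11.9), the AHR repressor AHRR (1.01 ± 0.205 to 4.42 ± 0.988), and STC2, a secreted glycoprotein (26.5 ± 1.53 to 70.3 ± 14.2). ATF4 and integrated stress response genes had 17 of 30 higher and 1 lower, 19 and 2 adjusted over the list alone, with a median of 0.61 (camera adjusted p = 1.19e-11; adjusted p = 0.0938 with an estimated correlation), including CTH of cysteine synthesis at 1.02 (SE 0.11) and GDF15 at 1.29 (SE 0.17). Immediate early genes had 15 of 31 higher and 2 lower, 21 and 3 adjusted over the list alone, with a median of 0.65 (camera adjusted p = 1.77e-08; adjusted p = 0.163 with an estimated correlation), such as ATF3 at 2.07 (SE 0.30). Over controls, the mean of immediate early genes was 0.45, 1.21 and 0.62 higher in PM2.5 replicates 1, 2 and 3, and that of NRF2 targets 0.37, 1.05 and 0.64 higher. NRF2 targets had 11 of 25 higher and 1 lower, 13 and 1 adjusted over the list alone, with a median of 0.37 (camera adjusted p = 2.05e-07; adjusted p = 0.208 with an estimated correlation). Sulfiredoxin SRXN1 was at 1.83 (SE 0.29), TXNRD1 at 1.32 (SE 0.21) and OSGIN1, an oxidative stress-induced growth inhibitor, at 1.51 (SE 0.23). NQO1 went from 97.6 ± 7.98 to 140 ± 18.7 (0.51, SE 0.11, adjusted p = 0.0126), but not past the threshold without control 3 (0.0553) or with group weights (0.0898). With group weights 6 NRF2 targets were called higher, as were 12 ATF4 and 12 immediate early genes.

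Targets of p53 rose in Nthy with 8 of 24 higher and 0 lower, 9 and 0 adjusted over the list alone, and a median of 0.37 (camera adjusted p = 1.32e-05; adjusted p = 0.0124 with an estimated correlation), with CDKN1A and the sestrin SESN2 (1.51, SE 0.25). NF-kB genes had 10 of 24 higher and 3 lower, 14 and 3 adjusted over the list alone, with a median of 0.56 (camera adjusted p = 0.00118; adjusted p = 0.372 with an estimated correlation). The cytokine LIF was at 1.57 (SE 0.22) and IL6 at 0.78 (SE 0.13), while the chemokine CCL5 was at -1.10 (SE 0.19). IL6 was not past the threshold with a pseudocount of 0.1 (adjusted p = 0.0768). Lysosome and autophagy genes had 9 of 34 higher and 1 lower, 10 and 3 adjusted over the list alone, with a median of 0.18 (camera adjusted p = 0.0017; adjusted p = 0.354 with an estimated correlation), among them the autophagy receptor SQSTM1 at 0.99 (SE 0.20). Cytosolic heat shock genes had 2 of 18 higher, HSPA6 and CRYAB, and 0 lower, the same adjusted over the list alone, with a median of 0.63 (camera adjusted p = 0.00477; adjusted p = 0.580 with an estimated correlation). Without PM2.5 replicate 2 the heat shock median was 0.01 (adjusted p = 0.239). The medians of NF-kB and lysosome genes were then 0.36 and 0.07, still past the threshold. With group weights the members called higher were 5 for p53 targets, 5 for NF-kB genes and 3 for lysosome and autophagy. Over controls, the mean of the heat shock list was 0.13, 2.31 and 0.56 higher in PM2.5 replicates 1, 2 and 3. That of the AHR list was 1.10, 1.31 and 1.07 higher. CRYAB, a small heat shock protein, lost its call without any 1 Nthy control (0.0762 to 0.0966) and with limma-voom (0.0741), and was at 1.46 without PM2.5 replicate 2 against 2.5 with all 3, and HSPA1B was at 49.3 ± 2.40 and 388 ± 495 (2.04, SE 0.70, adjusted p = 0.0703).

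The 9 lists that fell in Nthy included mitosis and G2/M genes, with 0 of 32 higher and 16 lower, 0 and 17 adjusted over the list alone, and a median of -0.55 (camera adjusted p = 9.53e-07; adjusted p = 0.0568 with an estimated correlation). The spindle factor TPX2 fell from 121 ± 3.52 to 60.4 ± 10.8 and CDCA8, a chromosomal passenger protein, from 60 ± 1.44 to 30.9 ± 6.38. DNA replication genes had 1 of 32 higher and 12 lower, 2 and 18 adjusted over the list alone, with a median of -0.35 (camera adjusted p = 0.000137; adjusted p = 0.163 with an estimated correlation), such as ribonucleotide reductase RRM2 at -0.85 (SE 0.15). The extracellular matrix and mesenchymal list had 0 of 38 higher and 15 lower, 2 and 16 adjusted over the list alone, with a median of -0.28 (camera adjusted p = 0.000181; adjusted p = 0.0393 with an estimated correlation), including tenascin TNC (52.0 ± 8.92 to 20.5 ± 1.44) and COL5A1 (20.9 ± 1.72 to 8.61 ± 1.08). Hypoxia and glycolysis genes had 3 of 31 higher and 14 lower, 4 and 17 adjusted over the list alone, with a median of -0.36 (camera adjusted p = 0.000748; adjusted p = 0.28 with an estimated correlation). Phosphoglycerate mutase PGAM1, with 13 named copies, was at -0.85 (SE 0.10). Epithelial junction genes had 0 of 13 higher and 7 lower, 1 and 7 adjusted over the list alone, with a median of -0.80 (camera adjusted p = 0.00242; adjusted p = 0.0938 with an estimated correlation). This list holds keratins beside junction genes, and the members did not move together. KRT7 fell from 276 ± 23.6 to 106 ± 15.5, and KRT18 from 398 ± 40.1 to 189 ± 12.7. KRT18 has 67 named copies and overlaps KRT8. Among members other than keratins, mean FPKM was lower with PM2.5 for JUP (27.2 to 15.3), PKP3 (11.2 to 6.19), TJP3 and CLDN4. The mean was higher for CLDN1 (30.2 to 39.7), TJP1 (3.75 to 5.86), OCLN (2.28 to 2.74), CLDN3 and DSP. None of these was called higher over all genes. With group weights the members called lower were 2 for DNA replication, 7 for hypoxia and glycolysis, 12 for mitosis and 2 for ovarian surface genes. Ovarian surface genes, which share KRT7 and KRT18 with the junction list, had 0 of 14 higher and 5 lower, also 0 and 5 adjusted over the list alone, with a median of -0.28 (camera adjusted p = 0.00992; adjusted p = 0.128 with an estimated correlation), and of -0.11 without PM2.5 replicate 2.

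Fibroblast and pericyte markers fell in Nthy with 0 of 8 higher and 4 lower, the same adjusted over the list alone, and a median of -0.33 (camera adjusted p = 0.0124; adjusted p = 0.314 with an estimated correlation), COL1A1 being 1 of the 4. Their median was -0.20 without PM2.5 replicate 2. Respiratory chain genes had 0 of 44 higher and 7 lower, also 0 and 7 adjusted over the list alone, with a median of -0.23 (camera adjusted p = 0.0017; adjusted p = 0.580 with an estimated correlation). Over controls, the mean of this list was -0.41, -0.43 and 0.13 in PM2.5 replicates 1, 2 and 3, so replicate 3 did not lie below the controls. The call was lost without PM2.5 replicate 1 (median -0.15, adjusted p = 0.0816), the median was -0.48 without replicate 3, and with group weights 1 member was called lower. ATP synthase subunit ATP5F1A was at -0.51 (SE 0.09). Thyroid genes had 0 of 9 higher and 4 lower, 0 and 5 adjusted over the list alone, with a median of -0.54 (camera adjusted p = 0.0297; adjusted p = 0.233 with an estimated correlation). The coactivator CITED2 was at -0.82 (SE 0.14). The call of the list was lost without PM2.5 replicate 3 (adjusted p = 0.123) or control 1 (0.0587) and under both other filters. With group weights 2 fibroblast and 2 thyroid members were called lower. The lists not past the threshold in Nthy were interferon-stimulated genes (1 of 28 higher, 9 lower, median -0.09, adjusted p = 0.107), apoptosis regulators (4 of 27 higher, 1 lower, 0.09, 0.0812), replication-dependent histones (0 of 11 higher, 2 lower, -0.14, 0.221) and ribosomal proteins (0 of 55 higher, 2 lower, -0.10, 0.221). ER chaperones had 1 of 23 higher and 4 lower (-0.06, 0.550), with the disulfide isomerase PDIA4 falling from 209 ± 10.8 to 104 ± 16.8. Steroidogenesis had 0 of 12 in either direction (0.03, 0.654), cholesterol synthesis 1 of 29 higher and 6 lower (-0.06, 0.731), mitochondrially encoded genes 1 of 13 in each direction (0.07, 0.827), and MYC and ribosome biogenesis genes 2 of 29 higher and 3 lower (-0.06, 0.977). TGF-beta and YAP targets had 2 of 20 higher and 5 lower (0.14, 0.977), and granulosa markers 0 of 6 in either direction with a median of -0.07 and a test pointing up (0.977). Adjusted over the list alone, higher and lower members numbered 1 and 11 for interferon-stimulated genes, 4 and 2 for apoptosis regulators, 0 and 0 for ribosomal proteins, 2 and 6 for ER chaperones, for cholesterol synthesis and for TGF-beta and YAP targets, 2 and 1 for mitochondrially encoded genes and 2 and 4 for MYC genes, and as over all genes for the other 3. IFIT1, an interferon-induced RNA-binding protein, fell from 11.5 ± 0.0362 to 5.37 ± 0.731.

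limma called 2399 of 15706 genes in Nthy, 782 higher and 1617 lower, and 294 of them changed at least 2-fold (116 higher, 178 lower). In 2353 of the 2399 every PM2.5 library lay on the same side of every control, which held for 28.2% of all genes tested against 10% by chance. On the first principal component (57.7% of the variance) PM2.5 replicates 1, 2 and 3 lay at 15.5, 63.3 and -10.9 and the controls at -26.8 to -16.4. On the second (23.1%) they lay at 5.49, 2.99 and -43.6 and the controls at 9.21 to 16.7, so replicate 3 stood apart there. Over protein-coding genes the SD of the log2 ratio to the controls was 0.375, 0.716 and 0.419, so by that measure replicate 1 lay nearest. The spread between PM2.5 libraries was 0.403 on the log2 scale, against 0.198 between Nthy controls and 0.199 between IOSE PM2.5 libraries. The simulation gave both Nthy groups their mean dispersion and had 46.7% false calls with 200 genes changed. That share cannot be carried over to the 2399 calls. With group weights 691 genes were called (181 higher, 510 lower), and all 691 were among the 2399. With Nthy fitted alone 3 genes were called, KRT81 (-2.17), the pseudogene RPL13AP20 (-1.84) and the microRNA gene MIR3181 (1.72), each at adjusted p = 0.0487, the last 2 chosen for naming after their values were seen. The count was 6596 without PM2.5 replicate 3 (2855 higher, 3741 lower), and 1403, 1177 and 1018 without controls 1, 2 and 3.

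**Figure D2:**
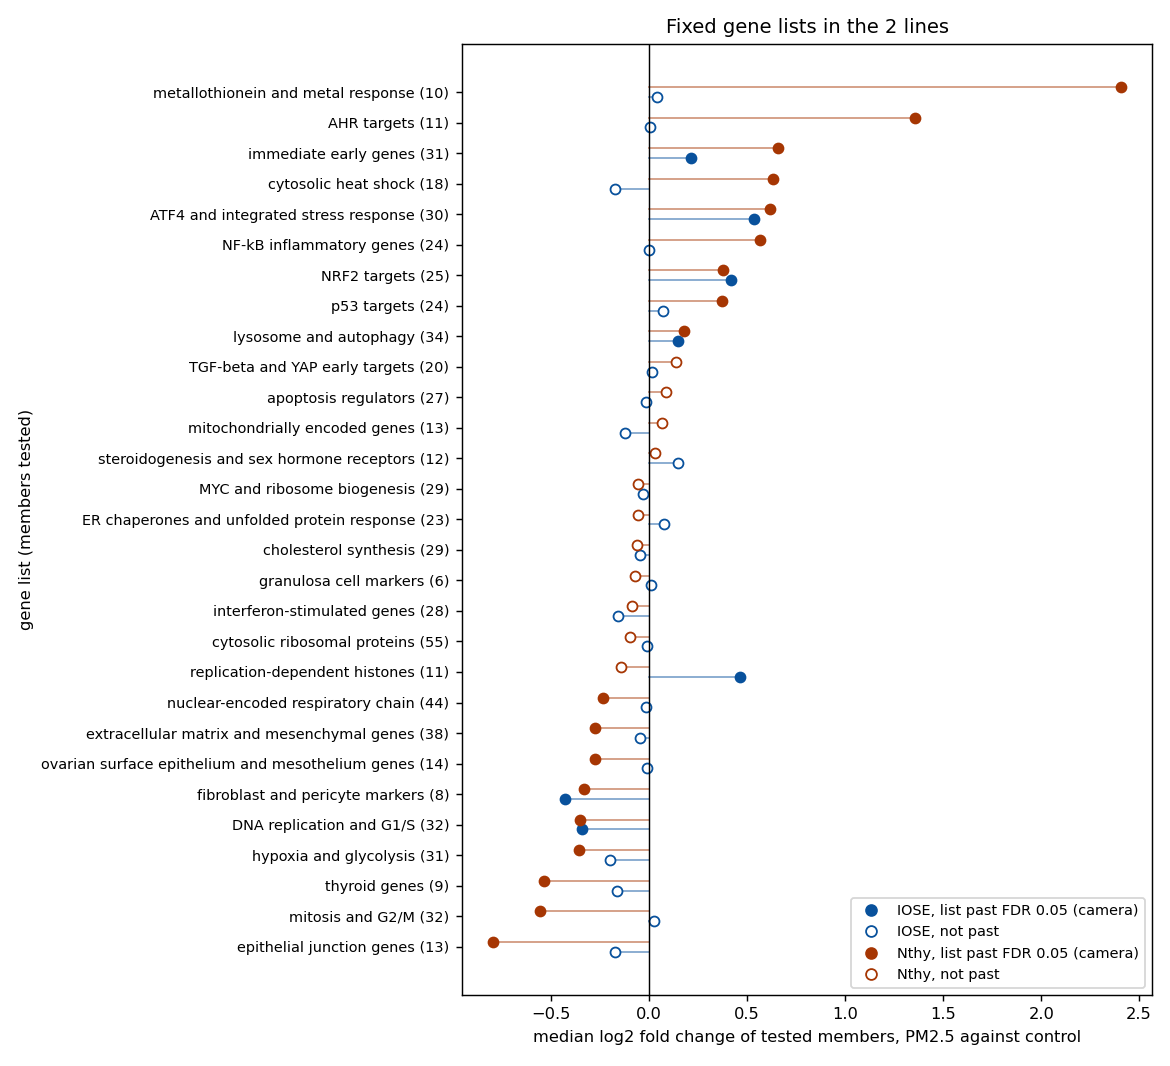
Median log2 fold change of the tested members of each fixed gene list in IOSE and in Nthy, with filled points for lists past a false discovery rate of 0.05 in limma's camera test. The metallothionein median was 0.04 in IOSE and 2.41 in Nthy, and the ATF4 medians were 0.53 and 0.61.

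**Figure D3:**
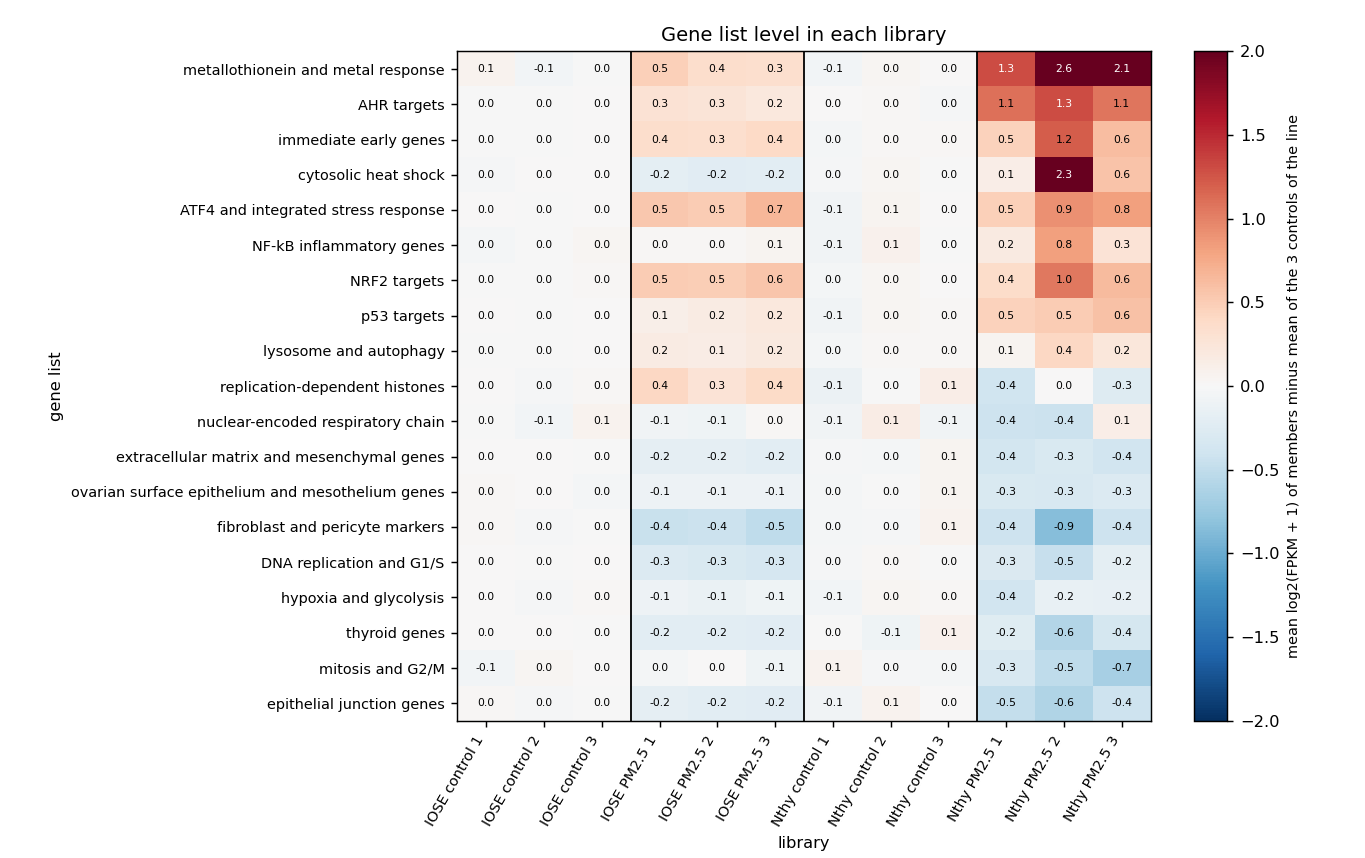
Mean log2(FPKM + 1) of each list in each library minus the mean of the controls of its line, for 19 lists (rows) and 12 libraries (columns). Heat shock genes stood at 0.13, 2.31 and 0.56 in Nthy PM2.5 replicates 1, 2 and 3, and AHR targets at 1.10, 1.31 and 1.07.

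In order to find genes that responded differently in the 2 lines, the Nthy effect minus the IOSE effect was tested, with positive values for a higher response in Nthy. On the side higher in Nthy were SLC30A2 and 2 metallothioneins, whose calls were all lost with limma-voom on the recovered reads. SLC30A2 differed by 3.07 (SE 0.39, adjusted p = 0.00378), MT1M by 4.40 (SE 0.64, adjusted p = 0.00803) and MT1F by 2.77 (SE 0.47, adjusted p = 0.0170), and both metallothioneins were listed at 0 in all IOSE libraries. SLC30A2, at 0.00521 in IOSE controls, and KRT81, at 0.0293, were below the filter in IOSE, so the difference of these 4 genes is the Nthy change beside a line without a measurable level. EGR1 differed by 2.55 (SE 0.50, adjusted p = 0.0342). MT-ATP8 (mitochondrial genome, 8366 to 8572) fell in IOSE and went from 18.9 ± 6.38 to 90.1 ± 72.5 in Nthy (1.92, SE 0.47, adjusted p = 0.0201), a difference of 4.38 (SE 0.66, adjusted p = 0.0095). On the other side were KRT81 at -2.28 (SE 0.19, adjusted p = 0.00053), SCNN1A at -1.83 (SE 0.23, adjusted p = 0.00353) and CD24, a surface glycoprotein, at -2.14 (SE 0.27, adjusted p = 0.00361). CD24 went from 3.10 to 7.18 in IOSE and from 3.68 to 1.2 in Nthy. TFRC differed by -1.82 (SE 0.32, adjusted p = 0.0179), and RPL26, a ribosomal protein gene with 14 named copies, by -2.11 (SE 0.37, adjusted p = 0.0191). With limma-voom the adjusted p was 0.371 for SLC30A2, 0.387 for MT1M, 0.609 for MT1F and 0.240 for KRT81, each the highest over the alternatives of that gene, whose lowest were 7.65e-06, 0.000404, 3.52e-05 and 1.86e-05. It was 0.0563 for EGR1 (0.00038 to 0.0902 over its alternatives). In each of the 5 the fold change with limma-voom kept its sign, at 4.24, 5.82, 3.02, -3.21 and 2.74. With the replicate number as a block, 5 of these genes kept their calls for the difference and 5 lost them. Some calls depended on single libraries. MT1F lost its call without IOSE PM2.5 replicate 1 or 3, IOSE control 1 or 2, or Nthy control 1 (0.0501 to 0.0546), EGR1 without any 1 IOSE library or Nthy control (0.0749 to 0.0902), TFRC without IOSE PM2.5 replicate 1, IOSE control 1 or Nthy control 1 (0.0580 to 0.0620), and RPL26 without any IOSE PM2.5 library, IOSE control 2 or 3, or Nthy control 1 or 2 (0.0508 to 0.0628). The Nthy call of MT-ATP8 was lost without Nthy control 1 or 2 (0.0645 to 0.0689) and with group weights (0.0650).

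Of the lists, 14 differed between the lines, 6 with a higher and 8 with a lower response in Nthy. AHR targets differed by a median of 0.65 with 4 of 11 members higher and 0 lower, 6 and 0 adjusted over the list alone (camera adjusted p = 1.04e-06; adjusted p = 0.0139 with an estimated correlation), with AHRR at 1.85 and CYP1A1 at 1.79. Metallothioneins differed by 1.58 with 4 of 10 higher and 0 lower, 4 and 1 adjusted over the list alone (0.000268; adjusted p = 0.230 with an estimated correlation), p53 targets by 0.26 (0.0102; adjusted p = 0.103 with an estimated correlation), NF-kB genes by 0.46 (0.0102; adjusted p = 0.618 with an estimated correlation), heat shock genes by 0.57 (0.00244; adjusted p = 0.646 with an estimated correlation) and immediate early genes by 0.31 (0.0350; adjusted p = 0.646 with an estimated correlation). Mitosis genes differed by -0.50 (1.04e-06; adjusted p = 0.0905 with an estimated correlation), and histones by -0.50 with 0 of 11 higher and 4 lower, 0 and 5 adjusted over the list alone (0.000268; adjusted p = 0.152 with an estimated correlation). The others below 0 were respiratory chain genes (-0.14, 0.00255; adjusted p = 0.646 with an estimated correlation), hypoxia genes (-0.16, 0.0196; adjusted p = 0.552 with an estimated correlation), ER chaperones (-0.23, 0.0300; adjusted p = 0.386 with an estimated correlation), epithelial junctions (-0.04, 0.0322), extracellular matrix (-0.15, 0.0350) and ovarian surface genes (-0.14, 0.0466), the last 3 at adjusted p = 0.230 with an estimated correlation. For the rest, higher and lower members numbered 1 and 0 of 24 for p53 targets, 0 and 0 of 24 for NF-kB genes, 0 and 0 of 18 for heat shock, 1 and 0 of 31 for immediate early genes, 0 and 1 of 32 for mitosis, 0 and 1 of 44 for the respiratory chain, 0 and 3 of 31 for hypoxia, 0 and 1 of 23 for ER chaperones, 0 and 3 of 13 for epithelial junctions, 2 and 5 of 38 for extracellular matrix and 0 and 2 of 14 for ovarian surface genes. In that order they were 2 and 0, 7 and 1, 2 and 0, 4 and 2, 0 and 4, 0 and 1, 0 and 8, 0 and 1, 0 and 3, 5 and 12, and 0 and 4 adjusted over the list alone. Listed at 0 in all IOSE libraries were 4 of the 10 metallothioneins, 4 of the 24 NF-kB genes and 4 of the 14 ovarian surface genes. With only genes above the filter in each line 7 lists differed, and NF-kB (median 0.34, adjusted p = 0.139), immediate early (0.29, 0.0758), hypoxia (-0.13, 0.0758), epithelial (-0.16, 0.117), extracellular matrix (-0.13, 0.381) and ovarian (-0.13, 0.234) lists did not. The 4 metallothioneins left, too few for the test, had medians of 0.76 in IOSE and 1.79 in Nthy. With limma-voom on the recovered reads the extracellular matrix median turned to 0.07 (adjusted p = 0.801). The same setting ended the calls of metallothioneins (0.185), NF-kB genes (0.136), epithelial junctions (0.136) and ovarian surface genes (0.180). The call of immediate early genes ended with GC correction (0.172) and with no filter (0.0879), that of extracellular matrix genes with a pseudocount of 0.1 (0.414), and that of ovarian surface genes with that pseudocount (0.0992), upper quartile scaling (0.0599), group weights (0.0678) and protein-coding genes only (0.0527). Without Nthy PM2.5 replicate 2 the calls of heat shock (median 0.22, adjusted p = 0.129), NF-kB (0.25, 0.0899), respiratory chain (-0.08, 0.0899), epithelial (-0.05, 0.129), immediate early (0.14, 0.184) and ovarian (-0.10, 0.184) lists were lost, and the metallothionein median was 0.83. Without Nthy PM2.5 replicate 1 this held for respiratory chain (median -0.04, adjusted p = 0.0651), hypoxia (0.254), ER chaperone (0.116), extracellular matrix (0.0651) and ovarian (0.0588) lists. It held without Nthy PM2.5 replicate 3 for ER chaperones (0.0643), extracellular matrix (0.0643) and ovarian genes (0.0800), without IOSE PM2.5 replicate 2 for ER chaperones (0.0542), extracellular matrix (median -0.09, adjusted p = 0.0582), immediate early (0.0632) and ovarian genes (0.0603), without Nthy control 3 for extracellular matrix (0.0526) and ovarian genes (0.0804), without Nthy control 1 for immediate early genes (0.0656), and without IOSE control 3 for ovarian genes (0.0837).

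For the lists not past the threshold of the difference, the median and camera adjusted p are given in turn. ATF4 genes, which rose in both lines, differed by 0.18 (0.205) and NRF2 targets by 0.15 (0.496). The values were -0.10 (0.0919) for ribosomal proteins, 0.18 (0.0997) for apoptosis regulators, -0.18 (0.169) for interferon-stimulated genes, -0.09 (0.276) for steroidogenesis, -0.08 (0.347) for MYC and ribosome biogenesis, -0.04 (0.383) for thyroid genes and -0.03 (0.432) for TGF-beta and YAP targets. They were 0.04 (0.632) for lysosome and autophagy, 0.03 (0.633) for mitochondrially encoded genes, -0.01 (0.682) for DNA replication and -0.04 (0.748) for granulosa markers. Cholesterol synthesis had a median of -0.02 and a mean of 0.03 (0.615), and fibroblast markers a median of -0.12 with a test pointing up (0.744). In single genes, limma called 270 differences, 135 higher and 135 lower in Nthy, 143 of them at least 2-fold. Of the 270 genes, 145 were above the filter in each line, and a fit of the 11892 such genes alone called 75. The count was 88, 126 and 91 without IOSE PM2.5 replicates 1, 2 and 3, 93, 102 and 108 without IOSE controls 1, 2 and 3, 778, 810 and 766 without Nthy PM2.5 replicates 1, 2 and 3, and 104, 122 and 127 without Nthy controls 1, 2 and 3.

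The overlap of calls was then compared between the lines, which share no library. GDF15, STC2 and the repressor BHLHE40 rose in both, by 1.64, 0.84 and 0.94 in IOSE and 1.29, 1.36 and 0.85 in Nthy. LDHA fell in both, at -0.65 in IOSE and -1.16 in Nthy. Over all genes 91 rose in both lines, against 21.4 for independent lists. The number that fell in both was 481, against 131. In opposite directions 15 rose in IOSE and fell in Nthy, against 44.3, and 11 fell in IOSE and rose in Nthy, against 63.5. The calls of both lines share 1 spread per gene and a trend with GC content, so the numbers for independent lists are not those of unrelated effects. Across the 15706 genes, which are not independent replicates, the fold changes of the lines correlated at r = 0.403 (Spearman 0.449). The correlation was 0.224 without Nthy PM2.5 replicate 2. With GC correction it was 0.295 (Spearman 0.329), with 560 genes called in the same direction and 53 in opposite directions. The 572 genes called in the same direction numbered 0 when each line was fitted alone, where Nthy had 3 calls. They numbered 201, 243 and 187 without IOSE PM2.5 replicates 1, 2 and 3, 145, 230 and 173 without IOSE controls 1, 2 and 3, 931 and 2410 without Nthy PM2.5 replicates 2 and 3, and 340, 326 and 233 without Nthy controls 1, 2 and 3.

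**Figure D4:**
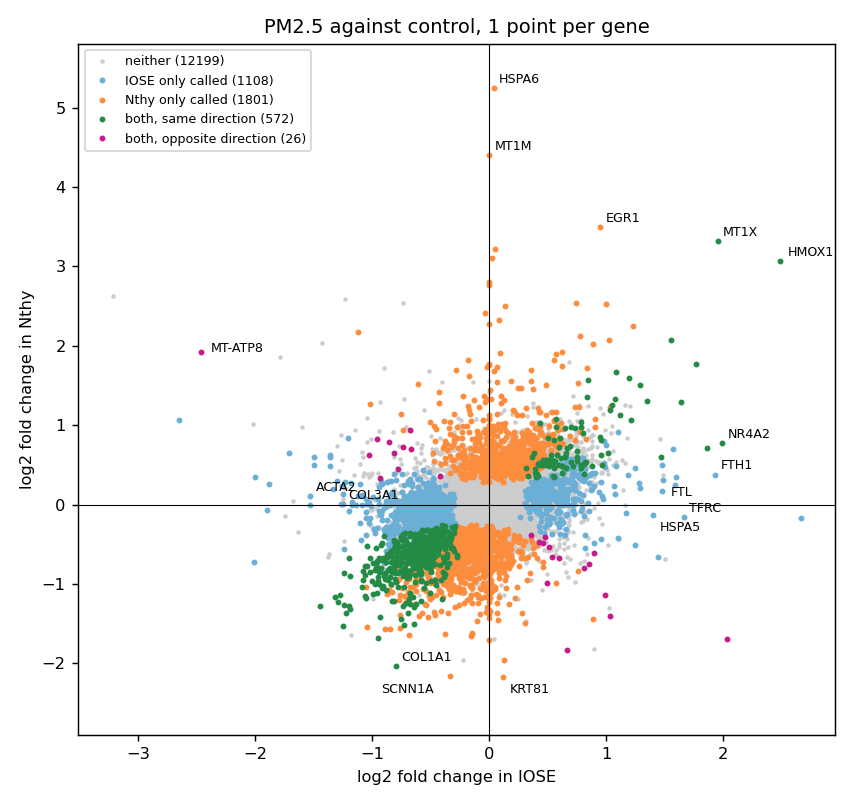
Log2 fold change of PM2.5 against control in IOSE (horizontal) and Nthy (vertical), where each point is 1 of 15706 genes, coloured by the lines in which it was called. Called in the same direction in both lines were 572 genes, and in opposite directions 26.

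Fold changes went with the GC content of genes in both lines. The protein-coding genes tested were divided by GC content into 5 groups of near equal size, and most of those called lower lay in the 2 groups of highest GC. In IOSE the median log2 fold change was 0.29, 0.10, -0.07, -0.21 and -0.31 from the lowest to the highest group, with 139 genes called higher and 9 lower in the lowest and 11 and 556 in the highest. In Nthy it was 0.19, 0.07, -0.04, -0.16 and -0.24, with 92 higher and 48 lower in the lowest and 79 and 564 in the highest. Spearman's rho across genes was -0.677 and -0.430. The slope per 10 points of GC was -0.252, -0.249 and -0.241 in IOSE PM2.5 replicates 1, 2 and 3, and -0.218, -0.418 and 0.113 in those of Nthy, against -0.106 to 0.061 in controls. After correction for GC content 1294 genes were called in IOSE, 964 of them among the 1706, and 3496 in Nthy, 2192 of them among the 2399. Of the IOSE genes that the naming rule took, those that lost their calls with the correction included OCLN, DERL3, THY1, NPC2, BOP1, C3, ATP5PO, AKR1C1, SERPINH1, RSAD2 and C19orf71, and all 7 IOSE lists kept theirs.

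**Figure D5:**
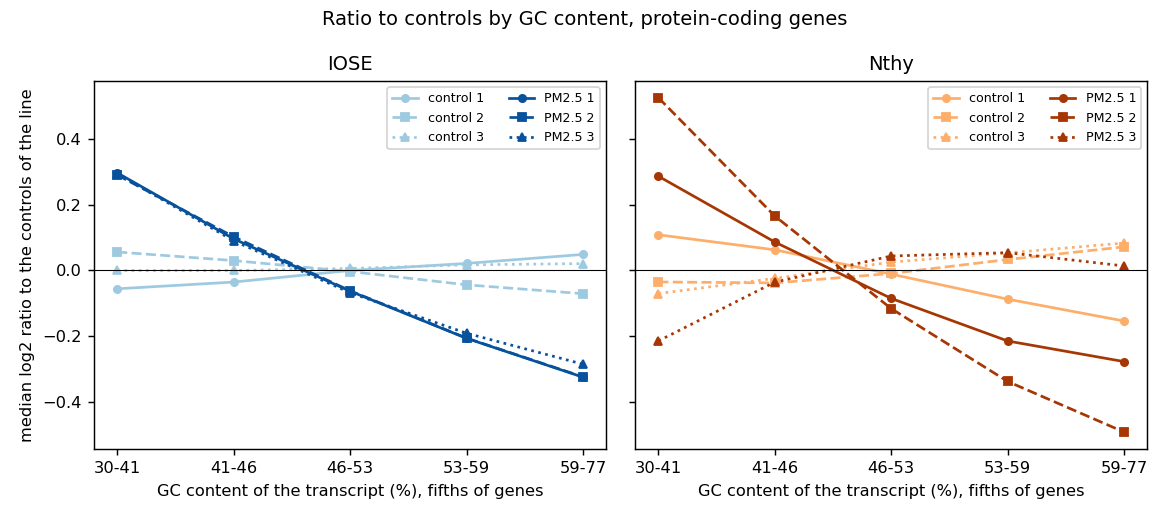
Median log2 ratio of each library to the controls of its line, in 5 groups by GC content of the protein-coding genes tested, with 1 line per library. The 3 IOSE PM2.5 libraries fell together from low to high GC, while Nthy PM2.5 replicate 3 (slope 0.113 per 10 points) ran against replicates 1 (-0.218) and 2 (-0.418).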

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

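The tests of library depth, of a mislabelled control and of genes above the filter in each line, and all list tests of the difference between lines, were chosen after the result was seen. Each value in the next paragraphs is the Nthy fold change minus the IOSE fold change on the log2 scale, for fixed lists and genes taken by the naming rule whose responses differed between the lines by the interaction test in limma.

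Higher in Nthy were the metallothioneins MT1M (4.40) and MT1F (2.77), the zinc exporter SLC30A2 (3.07), EGR1 (2.55), SERPINB2 (2.45), the antioxidant gene SRXN1 (2.01), AHRR (1.85), CDKN1A (1.81) and CYP1A1 (1.79). MT-ATP8 (4.38), the ribosomal protein gene RPS23 with 10 named copies (2.05), ACTA2 (1.63), COL3A1 (1.26) and LSS (0.94) also lay above 0. The IOSE call of RPS23 was lost without any 1 IOSE library (adjusted p from 0.0704 to 0.117). Below 0 were TFRC (-1.82), FTH1 (-1.56), HSPA5 (-1.53) and FTL (-1.18). Among keratins and surface genes KRT81 was at -2.28, CD24 at -2.14, SCNN1A at -1.83, KRT7 at -1.38, KRT8 at -1.28 and KRT18 at -0.77. Histones were at -1.61 (HIST1H2AC), -1.25 (HIST1H2BD), -1.21 (HIST1H1C) and -0.97 (HIST2H2BE), and matrix genes at -1.27 (TNC), -1.07 (COL8A1), -0.79 (COL5A1) and -0.68 (TGFBI). The others were RPL26 (-2.11), RRM2 (-0.97), the ATP synthase gene ATP5PO (-0.90), TPX2 (-0.85), IFIT1 (-0.84), NPC2 (-0.76), the mitophagy receptor BNIP3 (-0.73) and LDHA (-0.52). Of these, MT1M, MT1F and KRT7 were listed at 0 in all IOSE libraries, SLC30A2, SERPINB2, KRT81, TNC, COL8A1 and TGFBI were below the filter in IOSE, and COL3A1 was below it in Nthy, so their values are the change of 1 line. When only genes above the filter in each line were fitted, RPS23, LDHA, FTL, HIST2H2BE, HIST1H1C, RRM2, COL5A1, TPX2 and SRXN1 were no longer past the threshold (adjusted p up to 0.0588).

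List medians differed by 1.58 for metallothioneins, of which 4 of 10 were listed at 0 in IOSE, 0.65 for AHR targets, 0.57 for cytosolic heat shock, 0.46 for NF-kB genes, 0.31 for immediate early genes and 0.26 for p53 targets. They differed by -0.50 for mitosis and for histones, -0.23 for ER chaperones, -0.16 for hypoxia and glycolysis, -0.15 for extracellular matrix, -0.14 for respiratory chain and for ovarian surface genes, and -0.039 for epithelial junctions. Without Nthy PM2.5 replicate 2 they were 0.83 for metallothioneins, 0.22 for heat shock, 0.25 for NF-kB, 0.14 for immediate early and -0.08 for respiratory chain genes, and only the first of these was still past the threshold. With only genes above the filter in each line, 4 metallothioneins with a median difference of 0.80 were left, too few to test, and 7 of the lists still differed.

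Other splits of the same libraries were fitted in the same way. In each line the 6 libraries have 10 splits, too few for a share under 0.05. In IOSE the real split gave 1706 genes, the highest other 4, and 1 of the 10 splits gave as many. For lists it gave 7, the highest other also 7, and 4 of the 10 gave as many. In Nthy it gave 2399 genes (highest other 1, as many in 1 of 10) and 18 lists (highest other 14, as many in 1 of 10). For the difference between lines 100 of 200 splits were drawn, and 2 gave at least the 270 genes of the real one. This share argues only against libraries without any grouping by treatment, and not against equal responses of the lines. Splits that mix PM2.5 with control put the effect of a line into the residual spread, and called at most 4 genes in IOSE and 1 in Nthy. Their low counts were therefore fixed by the effect within each line and do not test whether the lines responded equally. The highest other split gave 4157 genes, several times the real count, and exchanged PM2.5 with control in one line, so that it tested the sum of both effects. For the 14 lists that differed, 18 of 100 splits gave as many (highest other 18), so chance cannot be excluded. The 572 genes called in the same direction were reached by 1 of 100 splits, the real one (highest other 26). For the same reason this argues only against libraries without any grouping by treatment. It says nothing of an overlap beyond that of unrelated effects. An absolute correlation as large as 0.403 came from 10 of 100 splits (highest other 0.553, range -0.489 to 0.553), so chance cannot be excluded.

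A first pattern was the fall of log2 fold change with GC content, by -0.247 (SE 0.00271) per 10 points in IOSE and -0.174 (SE 0.00389) in Nthy, with more genes called lower than higher. If a GC bias of the libraries were the whole source, the slope within ribosomal protein and respiratory chain genes should equal that of all genes, but over these 99 genes it was -0.155 (SE 0.0308) in IOSE and -0.0679 (SE 0.0303) in Nthy, closer to 0 by more than 2 SE. An offset of the authors' normalization stays open, since their scaling holds the median of all genes near 0. GC content was taken from the longest transcript of each gene, and errors in it could flatten the slope within those lists. That slope therefore sets no upper limit to a GC bias of the libraries. Such a bias may remain, and it would touch every gene of high or low GC content. An effect of PM2.5 on transcripts of different GC content stays open and was not tested further.

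A second pattern was the unequal response of the Nthy PM2.5 libraries, whose spread was 2.04 times that of Nthy controls, against 1.06 in IOSE. Depth was argued against, since the ratio was 2.02 after all libraries were thinned to the same number of reads. A control library carrying a PM2.5 label was argued against by the ATF4 list, whose mean in the lowest PM2.5 library lay 0.425 above that in the highest control. RNA from IOSE cells was argued against by 7 genes of that line without reads in Nthy controls, whose median was 0% of the IOSE level in the highest of the 3 libraries. Unequal exposure, harvest or RNA handling could each give such libraries, and the labels hold nothing that tests them.

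The last pattern was MT-ATP8, which fell in IOSE (-2.46) and rose in Nthy (1.92), while the overlapping MT-ATP6 stood at -0.01 and -0.11. The gene is 207 bases long, so a change in cDNA fragment length might alter its share of reads. Other tested features of at most 300 bases, 626 in number, had a median of -0.070 in IOSE and 0.0231 in Nthy, outside 95% of random lists in each line (-0.0185 to 0 and -0.00377 to 0.0190). These directions are consistent with a change in fragment length, but the medians are small beside the change of MT-ATP8. The values of MT-ATP6 (-0.01 and -0.11) argue against a change of a transcript that holds both genes. A regulated change of MT-ATP8 alone was not tested.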

How the results depend on the processing

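Tests with limma-voom, GC correction, protein-coding genes only, group weights and a filter within each line, and all list tests of the difference between lines, were chosen after the result was seen. DESeq2 and edgeR were not run, since the deposited values are FPKM, and of the count methods only limma-voom was run on the recovered reads. Size factor scaling was exactly 1 for every library and moved nothing, so it says nothing about stability. Upper quartile factors ran from 0.966 to 1.08.

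The IOSE count of 1706 genes was 6133 with each line alone, 6878 with group weights and 894 with a pseudocount of 0.1 and no filter, and 110 genes changed at least 2-fold. Without 1 library it ranged from 476 to 4109. The Nthy count of 2399 was 3 with each line alone, from 5107 genes at an unadjusted p under 0.05 in the fit of all libraries, 691 with group weights and 294 at a 2-fold minimum, and ranged from 1018 to 6596 without 1 library. The 270 differences between lines became 125 with a pseudocount of 0.1, 101 when the filter was also dropped, 79 with limma-voom, 75 with the filter within each line, 581 with GC correction and 143 at a 2-fold minimum, and ranged from 88 to 810. Fits with fewer samples have fewer degrees of freedom, which does not account for the rise of the IOSE count to 6133 and 4109. In the fit of all libraries the lines share 1 spread, and Nthy PM2.5 libraries varied most (0.403 on the log2 scale, against 0.188 to 0.199 in the other groups). Fitted alone, IOSE no longer carried that spread, and Nthy carried it undiluted with fewer degrees of freedom. The shares of these 2 in the fall of Nthy to 3 calls were not separated. For the other changes the cause was not tested.

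IOSE lists past the threshold numbered 7, and 0 with an estimated correlation, 14 with fry and 11 with a pseudocount of 0.1 and no filter. Nthy lists numbered 18, and 3 with an estimated correlation. The 14 lists that differed between lines became 1 with an estimated correlation, 9 with fry and 7 with the filter within each line, and ranged from 9 to 14 without 1 library. The 572 genes called in the same direction were 339 with no filter, 281 with a pseudocount of 0.1 and no filter, and 0 with each line alone, and ranged from 145 to 2410. The correlation of 0.403 was 0.167 with a pseudocount of 0.1 and no filter, and ranged from 0.224 without Nthy PM2.5 replicate 2 to 0.511 without replicate 3. The cause was not tested.

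Replicate numbers recur in each group of a line. Deviations of same-numbered libraries correlated at -0.0357, 0.0242 and 0.0129 in IOSE and 0.138, -0.157 and 0.147 in Nthy, which gave no clear sign of pairing. With 3 libraries per group these values cannot exclude it. Only 2 of the 6 IOSE and 2 of the 6 Nthy libraries correlated best with their own number, a hint from the data and not the design. With a replicate block the counts were 1009 in IOSE, 1527 in Nthy, 57 for the difference and 296 for the same direction.

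For the genes that the rule took, calls were kept in 3657 comparisons with an alternative, lost in 432 and turned in 0, and genes not called gained a call in 106 and stayed without in 568. With each line alone, 85 of 86 Nthy calls were lost. For lists, 938 calls were kept, 96 lost and 1 turned, the extracellular matrix list of the difference between lines, at 0.0704 with limma-voom (adjusted p = 0.801, and from 0.0110 to 0.801 over its alternatives). Depth limits the genes of low level, since 1 read on a gene of 1 kilobase was worth 0.0447 to 0.0632 FPKM.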

Other observations

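Further members of the fixed lists changed in ways that the comparisons above did not describe. In Nthy, the interferon-stimulated list was not past the threshold with camera (adjusted p = 0.107), while fry pointed down at adjusted p = 0.0016. Of its members, the RNA sensor OAS2 went from 6.49 ± 0.723 to 3.03 ± 0.581 FPKM and OASL from 51.6 ± 5.05 to 26.8 ± 7.43 (mean ± SD of 3 libraries, limma adjusted p = 0.00174 and 0.00413). OAS3 fell in IOSE from 25.5 ± 0.816 to 15.6 ± 1.06 (adjusted p = 0.00803). There 2 of 28 members were called higher, RSAD2 among them at 0.65, and 2 lower. The matrix genes TGFBI and LTBP2, both early targets of TGF-beta, fell in Nthy, from 58.7 ± 1.14 to 36.6 ± 1.06 and from 5.8 ± 0.821 to 2.89 ± 0.155. The calreticulin gene CALR, an ER chaperone, fell in Nthy from 427 ± 32.0 to 278 ± 25.9. Spermidine synthase SRM, of polyamine synthesis, went from 95.1 ± 8.24 to 60.7 ± 7.47. In IOSE the nucleolar GTPase GNL3 rose from 16.5 ± 1.67 to 27.0 ± 1.56, and ACLY, which makes cytosolic acetyl-CoA, fell from 114 ± 1.10 to 76.3 ± 5.02. The Nthy calls were lost when that line was fitted alone.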
